A study of Mus musculus with 11 samples.

How the data were processed

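Chromatin profiles of Myc-tagged RARα were measured by CUT&RUN in Prom1-enriched cortical progenitors of E14 mouse embryos, with digitonin at 0.05%, per the labels' protocols. The lists of 6 Myc-tag libraries, 3 control and 3 Foxc1 mutant, were used, and the groups and replicate numbers were taken from the titles. The 5 isotype libraries were not analysed here. Per the submitters' processing notes, the authors used SEACR and the genome build mm10. The version and settings of SEACR, the aligner, any filter of reads, the use of isotype libraries as a control and any scaling are not given in the sources used here. Each library has its own deposited peak list, so peaks were called per library and not on pooled replicates.

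Each deposited peak has a total signal and a max signal, in columns 4 and 5, and both are the authors' values. Their scaling is not stated. Within each library all max signals below 100 steps were whole multiples, within 0.01, of a single unit, called the step here. The step was 0.0500, 0.168 and 0.333 in control replicates 1, 2 and 3 and 0.147, 0.450 and 1.63 in mutant replicates 1, 2 and 3. Since a step is worth a different signal in each library, signal was used to rank peaks within a library and heights are given in steps, while signal between libraries was compared only after centring. The number of reads per library is not given in the sources used here. The signal summed over peaks moves with how much was called: it was 31.2 times higher in mutant libraries, while the covered length was 8.96 times and the step 3.38 times higher, as ratios of geometric means (exact permutation p = 0.2, 0.2 and 0.3). The depth behind each list is therefore unknown, and with 11869 peaks in the shortest list, and most of them 2 or 3 steps high, a region without a peak there is not shown to be unbound.

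Peaks on chromosomes 1 to 19, X and Y were kept, and 0 or 1 peak per library was left out. Lists of equal length held the 11869 peaks of highest total signal in each library. Genes came from a RefSeq table of GRCm38.p6, the assembly on which mm10 is built, with 21883 protein-coding genes, and all 318 symbols of the 15 gene lists were found in it. The table gives no strand, so windows around transcription start sites, which had been planned, were replaced by windows around both gene ends, of 5 kb for gene calls and 1 kb for the share of peaks at gene ends. Overlap counted from 1 bp. Random placement kept each peak's width and chromosome within the span covered by the 6 lists and was drawn 20 times with numpy instead of bedtools. For the overlaps of chosen regions, loci and tall gene end peaks under other observations it was drawn 100 times. The search for direct repeats of retinoic acid response elements was not run, because a genome sequence was not used here.

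Peak number (log2), median width and gene end share were compared with two-sided exact permutation tests over 20 labelled assignments, and the mean Jaccard index within minus between groups over 10 splits. Regions and genes called in one group alone were counted and set against the other splits of the libraries. Gene lists were compared by exact permutation tests on the percent of members called, with Benjamini-Hochberg adjustment over 15 lists, and within each library against 10000 random lists matched on gene length decile, adjusted over 90 tests. Signal in regions called in every full list was tested with limma, with a trend, on log2 of the highest max signal centred on each library's median. Equal-length lists had 0 such regions. The choice of tests, gene lists and named genes was made before the data were examined, except where the text says otherwise. The named-gene rule took Sox2, Hes1, Hes5, Notch1, Dll1, Rarb, Cyp26a1, Cyp26b1, Dhrs3 and Foxc1 in any case, up to 4 members per list by the number of libraries with a call and then by rank of total signal, the 10 genes of highest rank called in each group alone, the genes called in all libraries, and the genes nearest to the limma regions of smallest p. As no gene was called in all 6 libraries, the 6 called in 5 are named instead, chosen after their values were seen. The same holds for the region clusters and the genes at tall peaks.

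Alternatives tried were leaving out each library, a replicate block, full instead of equal-length lists, the top 5934 peaks, ranking by max signal, leaving out the highest 1% of peaks by max signal, 50% instead of 1 bp overlap, windows of 1, 5 and 25 kb, other normalizations, values and filters in limma, and unplaced contigs in the peak number. Alternatives added after seeing the data were loci of 500 kb, whole gene spans with 5 kb, lists of unchanged length without control replicate 2, and leaving out control replicates 2 and 3 together.

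The statistics were tested on simulated data. Of 195 planted regions that no control peak touched, 195 were found among the mutant regions. Identical intervals had been planted in every mutant list, so this checks the counting and not detection in real lists. Of 50 planted gene lists 50 passed p of 0.05, as did 2 of 50 unchanged lists. In 100 sets of 7 regions, limma called an 8-fold change in 100% of the sets and made 23 false calls among 600 unchanged regions. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.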

Results

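CUT&RUN, in which an antibody directs a nuclease to cut out the DNA around a bound protein, was applied to cortical neural progenitors of mouse embryos at E14. The cells had been enriched with magnetic beads for Prom1, a surface protein of neural stem and progenitor cells, and the antibody recognised the Myc tag on retinoic acid receptor alpha (RARα). RARα is a nuclear receptor that binds DNA as a partner of RXR receptors and responds to retinoic acid. The series compares control with Foxc1 mutant embryos; Foxc1 is a transcription factor needed for the meninges to form, and the series title names retinoic acid from the meninges, Notch and Sox2. The series lists 11 libraries, and the lists analysed here are those of the 6 Myc-tag libraries, 3 control and 3 Foxc1 mutant. The 5 isotype antibody libraries (3 control, 2 mutant) were not analysed here, so no background level from them stands beside the values. Nothing in the labels says that replicates came from separate embryos, so p-values measure the spread between these libraries only. With 3 libraries against 3, the two-sided exact permutation test cannot give a p below 0.1.

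The 6 lists differed in length by large factors within each genotype, and the genotypes did not differ by more than this spread. The control libraries held 86446, 11869 and 30273 peaks on the 21 standard chromosomes, and the mutant libraries 54112, 410562 and 513290. The mean log2 number of peaks was 14.94 ± 1.43 (SD, n = 3) in control and 17.78 ± 1.79 (SD, n = 3) in mutant libraries, a difference of 2.84 or 7.16-fold (exact permutation p = 0.2). Peaks covered 215, 3.95 and 8.68 Mb in the control libraries and 38.8, 328 and 417 Mb in the mutant libraries. The peak height, given in steps of the smallest signal unit of each library, had a median of 10, 2 and 2 in control and 4, 4 and 4 in mutant libraries. In control replicates 2 and 3, 93.2% and 93.3% of the peaks were 2 or 3 steps high. Without control replicates 2 and 3, which leaves a single control library and no test, the log2 difference in peak number was 1.38. Because of these lengths, the comparisons that follow use the 11869 peaks of highest total signal in every library unless stated otherwise.

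**Figure D1:**
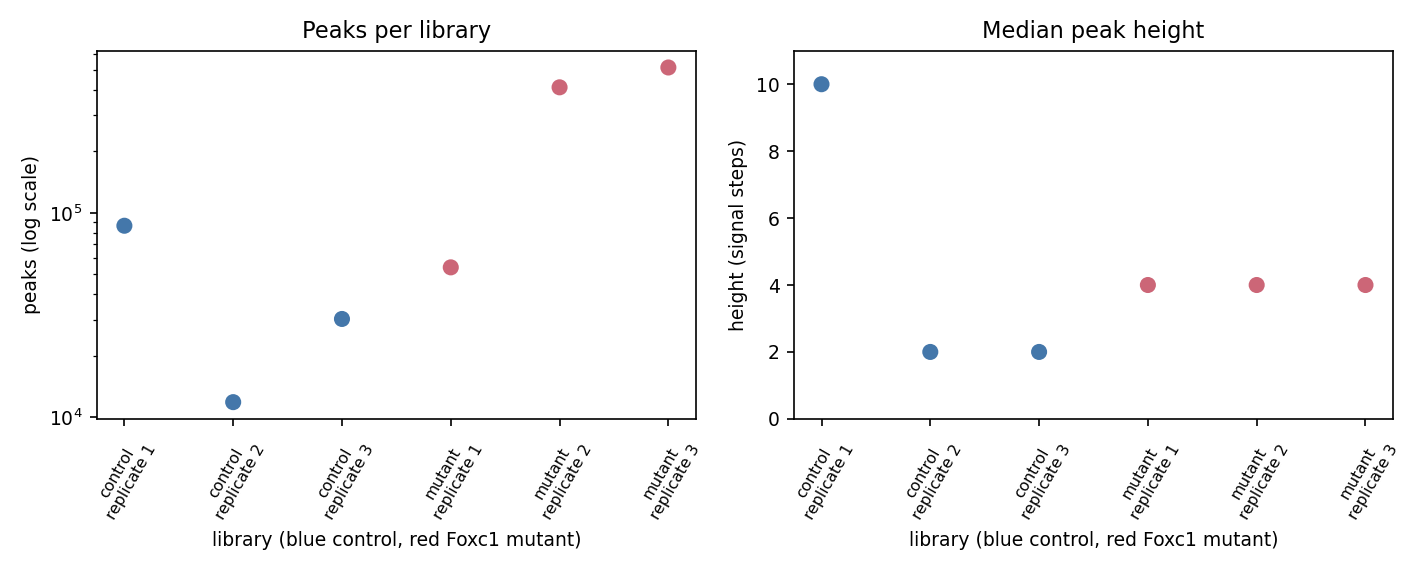
Number of peaks (left, log scale) and median peak height in signal steps (right) for each of the 6 Myc-tag libraries, control in blue and Foxc1 mutant in red, 1 point per library. Control peak numbers run from 11869 to 86446 and mutant numbers from 54112 to 513290, and control replicate 1 has a median height of 10 steps against 2 in the other control libraries.

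The genes named by the title of the series carried few peaks in either genotype, and so did most genes. In the equal-length lists 59.0% of the 21883 protein-coding genes had no peak in any library, and single libraries called 6.45% to 14.0% of the genes. Sox2, a transcription factor of neural stem cells, had no peak within 5 kb of either gene end in any of the 6 equal-length lists, and neither did Notch1, a Notch receptor, or Hes1, a transcriptional target of Notch. Hes5, another Notch target, had a peak 9 steps high in mutant replicate 3 alone, and Dll1, a Notch ligand, had a peak of 8 steps in the same library alone. The classical retinoic acid targets Rarb (a retinoic acid receptor), Cyp26a1 and Cyp26b1 (enzymes that degrade retinoic acid) and Dhrs3 (an enzyme that reduces retinaldehyde) had none in these windows in any equal-length list, and Foxc1 itself had none either. Rarb spans 651493 bp, and peaks inside it further than 5 kb from both ends were not counted. Its lack of a call therefore does not cover most of the gene. With all peaks, Hes5 and Rarb had peaks in both genotypes, of 11 steps each in control replicate 1 and of 3, 4 and 9 steps (Hes5) and 4, 5 and 8 steps (Rarb) in mutant replicates 1, 2 and 3. Cyp26b1, Dhrs3 and Foxc1 also had peaks of 11 steps in control replicate 1. In mutant libraries, Cyp26b1 and Dhrs3 had peaks of 4 or 5 steps in replicates 2 and 3, and Foxc1 had one of 4 steps in replicate 3. Sox2 (7 and 5 steps), Notch1 (5 and 6), Hes1 (4 and 5), Dll1 (5 and 8) and Cyp26a1 (3 and 4) had peaks in mutant replicates 2 and 3, the longest lists, and none elsewhere. In those full lists 90.2% and 91.6% of the genes had a peak in mutant replicates 2 and 3, against 58.4%, 6.65% and 16.1% in control replicates 1, 2 and 3 and 32.3% in mutant replicate 1. Presence in the full lists thus depended on list length, and no test of single genes was made on them.

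In each gene list fixed beforehand, the control and mutant libraries overlapped in the percent of members called, although the group means differed in most lists. Of the 22 retinoic acid pathway genes, 4.55% ± 4.55 (SD, n = 3) had a peak in control and 6.06% ± 2.62 (SD, n = 3) in mutant libraries (exact permutation p = 1). Among them, Tgm2, a transglutaminase induced by retinoic acid, was called in control replicate 2 (3 steps) and mutant replicate 1 (5 steps), and Rxra, the receptor partner, in mutant replicates 1 and 2 (5 and 8 steps). Rdh10, which makes retinaldehyde, and Rxrb, another partner receptor, were called in control replicate 1 alone, at 8 and 13 steps. Of the 36 Notch pathway genes, 6.48% ± 6.42 were called in control and 7.41% ± 6.99 in mutant libraries (SD, n = 3, exact permutation p = 1). Psen2, Psenen and Adam10, which belong to the proteases that cut Notch, were each called in a single library, Psenen at 18 steps in control replicate 1 and the others at 4 steps in mutant replicate 1. Of the 19 Sox genes, 7.02% ± 12.2 were called in control and 8.77% ± 10.96 in mutant libraries (SD, n = 3, exact permutation p = 1). Sox11, active in newborn neurons, had peaks of 5 and 12 steps in mutant replicates 2 and 3, while Sox12 and Sox4 were each called in control replicate 1 (11 and 13 steps) and mutant replicate 3 (8 and 7 steps). Sox10 was called in control replicate 1 alone, at 11 steps.

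Radial glia genes were called at 3.03% ± 2.62 in control and 10.6% ± 5.25 in mutant libraries (SD, n = 3, exact permutation p = 0.3), with Slc1a3, a glutamate transporter of radial glia, at 8 steps and Lhx2, a cortical transcription factor, at 4 steps in mutant replicate 1, and Id4, a regulator of progenitors, at 6 steps in mutant replicate 3. Neurogenesis genes were called at 12.1% ± 13.1 in control and 19.7% ± 9.46 in mutant libraries (SD, n = 3, exact permutation p = 0.6). Tbr1, a transcription factor of deep layer neurons, had peaks of 6 and 6 steps in mutant replicates 2 and 3, and Neurod2, a neuronal transcription factor, had peaks in control replicates 1 and 2 (10 and 2 steps) and mutant replicate 1 (5 steps). Tubb3 and Bcl11a were each called in control replicate 1 (10 and 12 steps) and mutant replicate 2 (5 and 6 steps). Cell cycle genes were called at 15.2% ± 6.94 in control and 6.06% ± 6.94 in mutant libraries (SD, n = 3, exact permutation p = 0.3). Top2a, a topoisomerase of dividing cells, was called in control replicates 1 and 3 (9 and 2 steps), and Cdk6, a kinase of G1 phase, in control replicate 3 and mutant replicates 1 and 3 (5 steps in each). Pcna was called in control replicate 2 (3 steps) and Cdk4 in control replicate 1 (7 steps), and both in mutant replicate 3 (6 steps in each). Wnt pathway genes were called at 5.56% and 8.89%, Hox genes at 1.71% and 0.855%, and housekeeping genes at 9.72% and 15.3% in control and mutant libraries. Marker lists of other cell types gave 2.08% and 4.17% for meningeal fibroblasts, 2.38% and 4.76% for vessel cells, 8.33% and 0% for microglia, 11.1% and 8.33% for ventral interneurons and 3.03% and 3.03% for erythroid cells. Genes active mainly in other organs were called at 11.1% in control and 2.78% in mutant libraries. Across the 15 lists, 9 were higher and 5 lower in mutant libraries. The direction of the retinoic acid, Notch, Sox, Wnt, Hox, housekeeping, vessel and ventral interneuron lists turned when one or another library was left out. With all 6 libraries no list had groups that did not overlap, and the adjusted p of the exact permutation tests was 1 for every list. Chance separates at most 10% of lists for 3 against 3, and fewer where libraries tie. The retinoic acid list had 2, 1 and 0 members called in control and 2, 1 and 1 in mutant replicates 1, 2 and 3. With these ties no split could have separated its groups, so its overlap shows nothing.

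**Figure D2:**
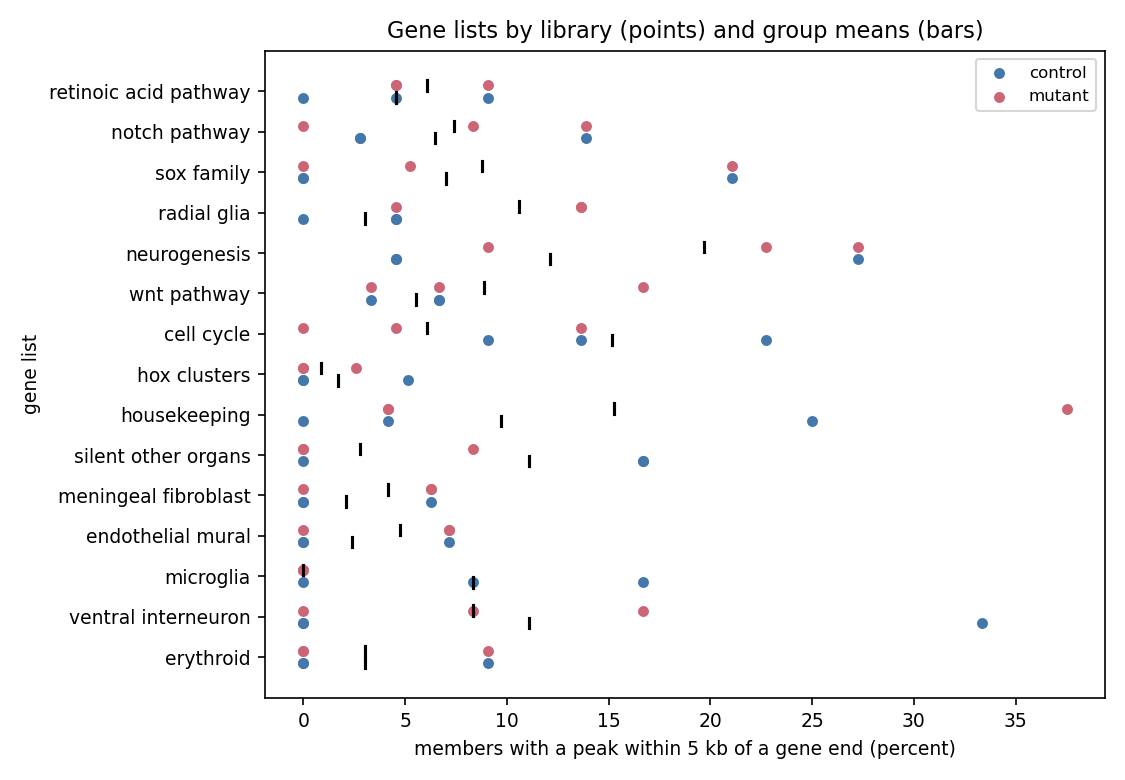
Percent of members of each of the 15 gene lists with a peak within 5 kb of a gene end in the equal-length lists, 1 point per library (control blue, Foxc1 mutant red), with black bars for group means. Control and mutant points overlap in every list; the highest housekeeping value is 37.5%, in mutant replicate 3.

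Within single libraries, 1 of the 90 list by library tests passed correction. In mutant replicate 3, 9 of the 24 housekeeping genes had a peak, against 2.20 in random lists of matched gene length (adjusted p = 0.0090, permutation p = 0.0001, the smallest that 10000 random lists can give). They included Gpi1, an enzyme of glycolysis, at 11 steps, and Eif4a1, a translation factor, and Actb, the cytoskeletal actin, at 6 steps each. Neurogenesis genes in mutant replicates 2 (5 of 22) and 3 (6 of 22) had permutation p = 0.0139 and 0.0194 and an adjusted p of 0.582 for both. The housekeeping genes in the other mutant libraries were called at 4.17% in each, and in control libraries at 25%, 0% and 4.17%.

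Genes called in all 3 libraries of a genotype and in no library of the other were 11 for control and 39 for mutant. The named control genes had peaks of 2 to 4 steps in control replicates 2 and 3 and of 10 to 46 steps in replicate 1, with Galk2, a sugar kinase, at 12, 2 and 3 steps, Sp110, a nuclear body protein, at 46, 3 and 3 steps, and Rad23b, a DNA repair protein, at 12, 2 and 4 steps in replicates 1, 2 and 3. The other control genes among the 10 of highest rank were Efcab14, Olfr699, Snx7, Klk15, Prr15, Dusp15 and Arpc2. These genes were not free of peaks in mutant libraries, as all 11 had peaks in 2 or 3 of them in the full lists, Galk2 at 3, 6 and 6 steps, Sp110 at 4, 9 and 9 steps and Rad23b at 4, 5 and 6 steps. Of the 10 mutant genes of highest rank, 9 were Ugt1a genes (Ugt1a1, Ugt1a2, Ugt1a5, Ugt1a6a, Ugt1a6b, Ugt1a7c, Ugt1a8, Ugt1a9 and Ugt1a10), which encode enzymes that conjugate glucuronic acid and share most of their exons, so that these 9 calls are 1 stretch of peaks. The remaining gene, Mroh2a, lies next to them. The best peaks there were 7, 16 and 20 steps high in mutant replicates 1, 2 and 3, and no control library had one in the equal-length lists. In the full lists Ugt1a5 had a peak of 8 steps in control replicate 1. Most of the 39 mutant genes had no control peak in the full lists, but some of lower rank did. In control replicate 1 Tmem267 had 23 steps and Eya1 18 steps, against 7, 12 and 13 and 4, 6 and 5 steps in mutant replicates 1, 2 and 3. Random placement of the same peaks gave 10.8 ± 3.47 control genes and 13.8 ± 3.06 mutant genes (SD over 20 placements). There were 1 control and 20 mutant genes with windows of 1 kb, 1 and 1755 with all peaks, and 23 mutant genes without the highest 1% of peaks by max signal. The direction turned with windows of 25 kb (162 control and 150 mutant genes). Without control replicate 1, 2 or 3 more control than mutant genes were counted (133 and 51, 453 and 146, and 117 and 43). Without mutant replicate 1, 2 or 3 the mutant count was 163, 160 and 123 and the control count 12, 12 and 17. In the group that lost a library fewer libraries had to share a call, which by itself raises its count. Counts without a library therefore cannot show whether the direction holds. Other splits of the 6 libraries gave up to 53 genes in total, against 50 for control and mutant. No gene was called in all 6 libraries, and 6 were called in 5 of them: Gm7592, Lrrn3, Zfp668, Cdh7, Iws1 and Arid4b.

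At the level of regions, 79 were called in the 3 mutant and no control library, and 9 in the 3 control and no mutant library, among 67204 merged regions of which 94.9% were called in a single library. The mutant regions lay close together. On chromosome 13, 16 of them lay between 12764050 and 12943060 near the prolactin family gene Prl2c3, where 2 more regions of this stretch, from 12797316 to 12799606 and from 12802050 to 12810944, also held peaks of control replicate 1, 13 and 20 steps high. On chromosome 4, 13 lay between 147334681 and 147611403 across the zinc finger genes Zfp978, Zfp982 and Zfp985, and 5 more between 146053215 and 146535487 across Zfp987, Zfp600, Zfp992, Zfp981 and Zfp993. On chromosome 1, 6 lay between 88210965 and 88310924 over the Ugt1a genes, Mroh2a, Hjurp and Trpm8, and on chromosome 16, 5 lay between 3232389 and 3274276, over no annotated protein-coding gene (coordinates in mm10). Among the control regions, those inside genes were at Msra, Stk31 and Sox6, the last 3177 bp wide with peaks of 15, 2 and 3 steps. Random placement gave 3.25 control and 3.50 mutant regions. More control than mutant regions were counted without control replicate 1 (634 control and 85 mutant regions), 2 (819 and 139) or 3 (167 and 80). Without mutant replicate 1, 2 or 3 there were 386, 247 and 257 mutant regions. As for genes, a group that lost a library needed fewer shared calls, so these counts cannot show whether the direction holds. With all peaks there were 25 control and 5962 mutant regions. Counted as loci, with regions under 500 kb apart taken as 1, the mutant regions made 30, and without the highest 1% of peaks by max signal 13 regions were left.

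Pairs of libraries of the same genotype did not share more sequence than pairs of different genotypes beyond what other splits gave. The Jaccard index, the shared length as a percent of the joint length, averaged 0.924% within and 0.380% between genotypes, a difference of 0.544 that 2 of the 10 splits reached (exact permutation p = 0.2). This difference was 1.22 without control replicate 1, 0.129 without control replicate 2 and 0.315 without control replicate 3. It was 0.299 without the highest 1% of peaks by max signal and 0.967 as the share of peaks overlapped by 50%. Control replicates 2 and 3 overlapped at 2.12%, 26.5 times the value of random placement. The mutant libraries overlapped each other at 2.53 to 3.81 times random placement, and control replicate 1 overlapped them at 1.67 to 2.01 times. Control replicate 1 overlapped control replicates 2 and 3 at 0.799 and 0.737 times random placement. The overlap of same-genotype libraries was thus carried in the control group by a single pair.

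**Figure D3:**
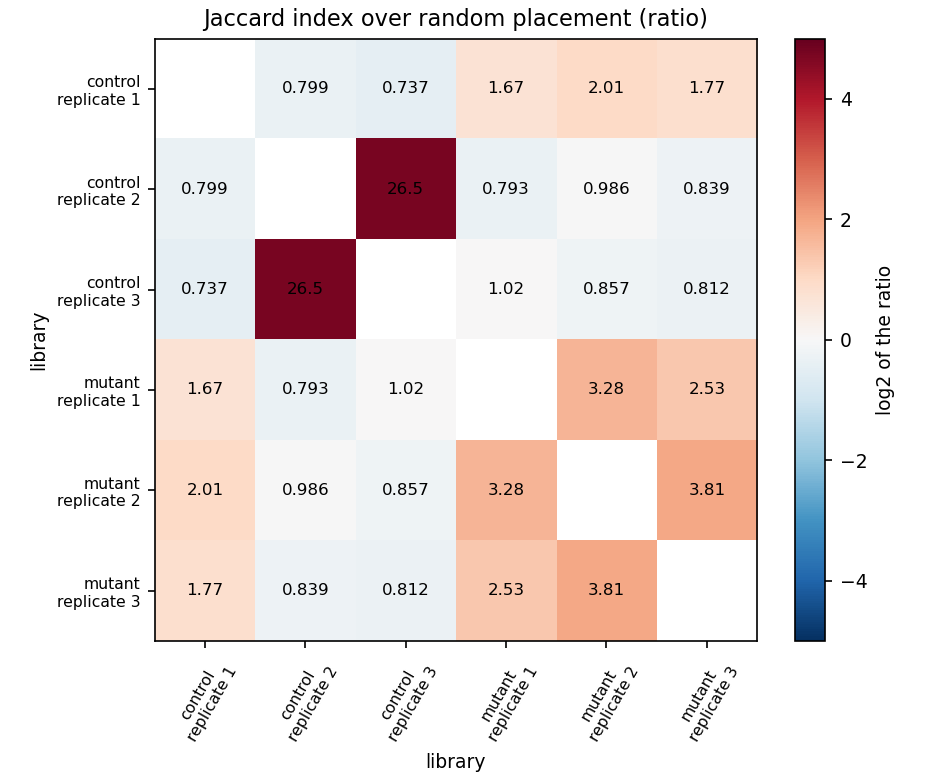
Jaccard index of each pair of equal-length lists divided by its value after random placement (number in each cell; color, log2 of that ratio). The pair of control replicates 2 and 3 stands at 26.5, mutant pairs at 2.53 to 3.81, and control replicate 1 with the mutant libraries at 1.67 to 2.01.

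Peaks were not placed differently relative to genes in the 2 genotypes by more than the spread between libraries. In the equal-length lists, 12.3%, 2.49% and 2.39% of the control peaks and 4.09%, 4.46% and 10.001% of the mutant peaks touched a window of 1 kb around a gene end, with means of 5.72% ± 5.68 and 6.18% ± 3.31 (SD, n = 3, exact permutation p = 1). Against random placement these shares were 1.47, 0.711 and 0.680 times as high in the control and 0.970, 0.853 and 1.82 times as high in the mutant libraries. Without mutant replicate 3 the difference of 0.463 percentage points became −1.44, and without control replicates 2 and 3, with a single control library left, it became −3.78, so its direction rests on these libraries. The median peak width was 1456 ± 1940 bp in control and 1420 ± 551 bp in mutant libraries (SD, n = 3, exact permutation p = 1), and the difference of −35.7 bp became 1084 bp without control replicate 1.

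Peaks of 10 to 15 steps in mutant replicate 3 lay at gene ends more often than low ones, a comparison chosen after the data had been seen. Of its peaks 2 or 3 steps high, 3.81% touched a gene end, against 18.9% of those 10 to 12 steps high (95% Wilson interval 16.7 to 21.4) and 40.7% of those 13 to 15 steps high (33 of 81, interval 30.7 to 51.6), where random placement gave 5.37%. Its peaks of 21 steps and more did so at 3.45% (1 of 29, interval 0.611 to 17.2). In mutant replicate 2 the share was 5.04% at 10 to 12 steps (interval 3.51 to 7.18) and 11.9% at 13 to 15 steps (5 of 42, interval 5.19 to 25), and in mutant replicate 1 it was 12.1% at 10 to 12 steps (4 of 33, interval 4.82 to 27.3). In control replicate 1 it was 7.97% at 10 to 12 steps (interval 7.69 to 8.26) and 8.03% at 13 to 15 steps. Such heights are ordinary there, as 55.5% of its peaks were 10 or more steps high. In mutant replicates 1, 2 and 3 this held for 0.107%, 0.156% and 0.235% of the peaks. The same bin thus holds unlike parts of these lists. The intervals cover counting error only.

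**Figure D4:**
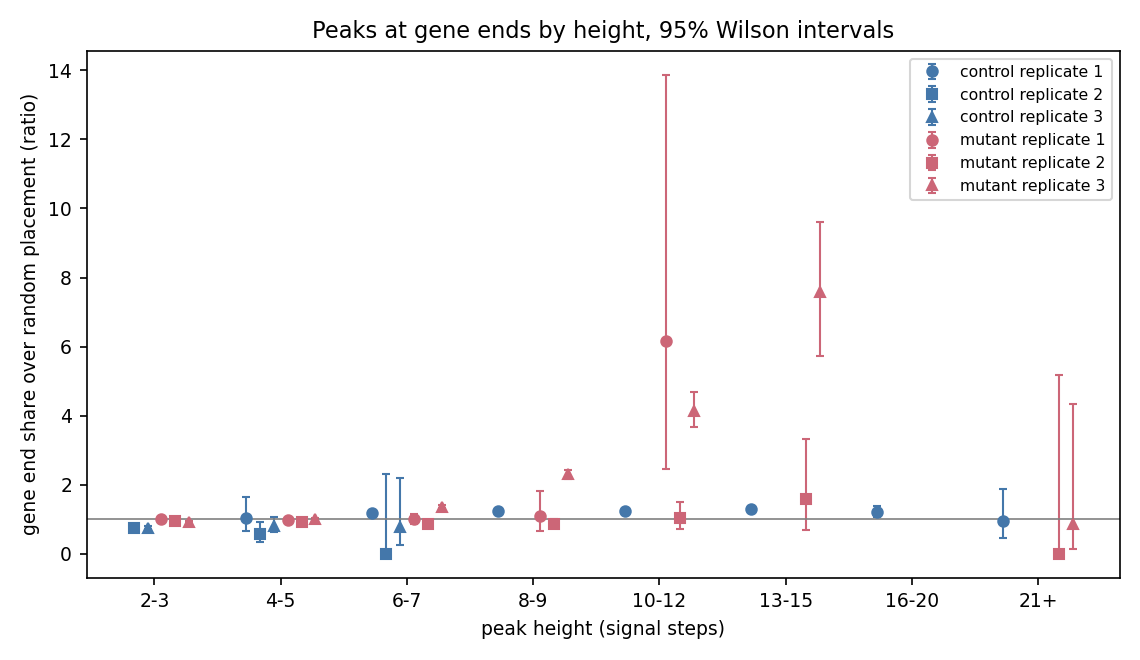
Share of peaks that touch 1 kb around a gene end, divided by its value after random placement, against peak height in signal steps, for all peaks of each library (control blue, Foxc1 mutant red), every bin of at least 20 peaks and 95% Wilson intervals. Mutant replicate 3 reaches 4.15 at 10 to 12 steps and 7.59 at 13 to 15 steps and stands at 0.870 from 21 steps, mutant replicate 1 stands at 6.15 at 10 to 12 steps with 33 peaks, and mutant replicate 2 at 1.05 and 1.59.

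Signal could be compared in only 7 regions, those with a peak in all 6 full lists. They lie near or in Nup35, Pdk4, Agbl1, Usp17le, Gm9222, Fgf10 and Gm6712, on chromosomes 2, 6, 7, 7, 12, 13 and 17. After centring each library, the region 656030 bp from Nup35 (chromosome 2, 81316102 to 81318255) had a log2 fold change of −0.77 ± 0.38 (SE) between mutant and control, and the region 35108 bp from Pdk4, a kinase of pyruvate metabolism, one of 0.33 ± 0.23 (SE). None of the 7 passed limma with Benjamini-Hochberg adjustment (smallest adjusted p = 0.463), and none had an unadjusted p under 0.05. In simulated sets of 7 regions an 8-fold change was called in 100% and a 2-fold change in 65% of the sets. The simulated values were continuous, with a common spread and no floor. In the real regions control replicate 3 was 2 steps high throughout, the lowest height in its list. These rates therefore need not hold for the real regions.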

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

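Leaving out control replicates 2 and 3 together, the 500 kb loci, the whole gene spans and the lists of unchanged length were chosen after seeing the data. Of 321 alternatives over 25 results, 247 did not turn their direction or stayed within 1.5 times the count. This number includes differences that fell to 0. Replicate blocks are counted in it too, although with equal pairs they cannot move a difference of means. It also includes all 13 alternatives for erythroid genes, whose difference of 0 with all libraries has no direction to keep. Exact permutation p-values could not fall under 0.1 here and say nothing about stability. Peak number (2.14 to 3.87 log2 without each library) and overlap within minus between groups kept their direction in every alternative run, and the limma count stayed 0. The replicate block could not move the peak number difference. Unplaced contigs and a cut at each library's median total signal could hardly move it. The size of the overlap difference moved between 0.129 (without control replicate 2) and 1.22 (without control replicate 1) from 0.544. Leaving out each library moved the width difference between −580 and 1084 bp (above 0 without control replicate 1 or mutant replicate 1) and the gene end share difference between −1.44 and 3.75 points (below 0 without control replicate 2 or 3 or mutant replicate 3). That share difference was also −0.243 with all peaks, −0.0284 without the highest 1% by max signal, −0.222 with a window of 5 kb and −3.78 without control replicates 2 and 3; the cause was not tested. Regions called in one group alone ranged from 9 to 819 (control) and 80 to 386 (mutant) without each library, and genes from 12 to 453 and 43 to 163. Without a library of the group itself fewer libraries had to share a call, and without control replicate 2 the equal-length lists also grew to 30273 peaks, with 819 control and 139 mutant regions and 453 and 146 genes. At the unchanged length of 11869 peaks these were 145 and 79 regions and 110 and 40 genes. With all peaks, regions numbered 25 and 5962 and genes 1 and 1755. Without control replicates 2 and 3, regions numbered 39873 and 350 and genes 2620 and 427, as a single control library was left. The top 5934 peaks gave 2 control regions and 3 control genes. Without the highest 1% by max signal 13 mutant regions and 23 mutant genes were left, and as loci of 500 kb 30 mutant regions. Windows of 1 kb gave 1 control and 20 mutant genes, windows of 25 kb 162 and 150, and whole gene spans with 5 kb 82 and 96. Gene lists whose groups did not overlap numbered 0 to 2 without each library, where chance gives at most 20% of the 15 lists or 3. They numbered 1 with the top 5934 peaks, ranking by max signal, windows of 25 kb or whole gene spans with 5 kb. There chance gives at most 10% or 1.5, and ties between libraries lower these values. Without each library, list differences ranged from −0.758 to 5.30 points for retinoic acid genes, −2.31 to 4.63 for Notch, −6.14 to 8.77 for Sox, −0.556 to 6.11 for Wnt, −7.26 to 0.855 for Hox, −5.56 to 13.2 for housekeeping, −3.57 to 4.76 for vessel, −8.33 to 8.33 for ventral interneuron and −15.2 to 3.03 for erythroid genes (0 with all libraries). They kept their direction but ranged from 6.06 to 17.4 for radial glia, 3.79 to 15.2 for neurogenesis, −12.9 to −5.30 for cell cycle, −20.1 to −5.56 for other organs, −12.5 to −5.56 for microglia and 1.04 to 4.17 for meningeal fibroblast genes. With all peaks, differences turned to 42.4 (cell cycle), 36.8 (Hox), 33.3 (other organs), 44.4 (microglia) and 41.7 (ventral interneuron) points, following list length. They also turned for Hox genes ranked by max signal (3.42), neurogenesis genes with windows of 1 kb (−1.52) and microglia genes over whole spans with 5 kb (2.78). Under a replicate block the peak number difference is 2.84 by construction, and only its p could change (exact sign-flip p = 0.5, smallest possible 0.25). Limma with this block still called 0 regions. Libraries of the same number did not deviate together (correlations −0.0765, −0.0839 and −0.0574 over bins of 1 Mb). This compares peak placement only and cannot tell whether a number marks a shared day or litter. The limma fit on equal-length lists had 0 regions and gave no value, and motif alternatives were not run. What depth limits was not measured, as reads per library are not given in the sources used here.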

Other observations

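The tests in this part were chosen after the results they bear on had been seen, except the overlap of tall gene end peaks with mutant replicate 2, which was set out before its value was known, and the counts of regions and genes in equal-length lists against other splits, planned before the data were examined. The 33 gene end peaks of 13 to 15 steps in mutant replicate 3 lay at 37 genes. Examples, chosen after their values were seen, are Clasp1, which stabilises microtubules, at 15 steps, Cltc, the clathrin heavy chain, Rpl38, a ribosomal protein, Rala, a small GTPase, and Tmed2, a protein of early secretory transport, at 14 steps, and Hadha and Hadhb, enzymes of fatty acid oxidation that share a peak, Dld, a dehydrogenase subunit, Top3b, a topoisomerase, and Tars, a transfer RNA synthetase, at 13 steps. None of the 318 genes of the fixed lists had a gene end peak of 10 to 15 steps in this library, housekeeping genes included (0 of 24, 0.305 expected), so the housekeeping excess in the equal-length list comes from lower peaks or from peaks further than 1 kb from a gene end. The 157 genes within 5 kb of the regions shared by control replicates 2 and 3 hold 0 members of the 15 lists.

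Control replicates 2 and 3 shared 1186 regions, with 10.02% of the peaks of replicate 2 overlapping a peak of replicate 3, and the shared length fell from 273429 bp to 17570 bp when the peaks of replicate 3 were shifted by 1 kb. Fragments shared between the libraries would leave identical peak boundaries, but 0.667% of the overlapping pairs had an identical start or end. Sites where any library piles up reads would also hold peaks of mutant replicates 2 and 3, and these overlapped the shared regions 0.969 times as often as random placement. Coordinates of another genome build could also give such a pattern. The gene end share of the 2 libraries lay below that of shifted peaks, 3.38 standard errors away in replicate 2 and at −5.74 standard errors in replicate 3. In replicate 2 this stays under the bound of 4. In mutant replicates 1 and 2 the distance was only −0.542 and 0.198 standard errors. A small distance thus need not mark another build, the measure cannot decide, and this was left open. A source common to control replicates 2 and 3 and a property of control cells both stay open, as peaks of control replicate 1 overlapped 96 of the regions against 117 at random, and a single library excludes nothing.

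In mutant replicate 3, 20.4% of the peaks 10 to 15 steps high touched a gene end, 4.60 times random placement. The share was 7.99% in control replicate 1, where such heights are ordinary, and 5.52% in mutant replicate 2. Whether depth plays a part was not tested, as reads per library are not given in the sources used here. The mutant genotype would raise the share in all 3 mutant libraries, and 12% was set as the bound for that. In mutant replicate 2 the upper bound of 7.65% lay below it. Mutant replicate 1 had 11.1% (4 of 36 peaks, 2.67 times random placement) with an upper bound of 25.3%. As an exclusion needed both of these libraries under 12%, the genotype stays open. Peaks of mutant replicate 1 and control replicate 1 overlapped the 238 gene end peaks 1.95 and 1.80 times as often as random placement, while those of control replicates 2 and 3 overlapped 1 and 0 of them against 1.75 ± 1.37 and 4.59 ± 2.07 (SD) at random. Those of mutant replicate 2 did so 1.35 times as often, between the bounds of 1.2 and 1.5, so whether it may hold the same promoters more weakly was not decided.

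The regions called in mutant libraries alone lay in clusters, with 45 of the 79 (57.0%) in 5 loci that hold 5 or more regions each, among them families of similar genes (Ugt1a, Zfp, Prl2c). The tallest mutant regions lay outside these 5 loci. In mutant replicates 1, 2 and 3 they reached 118, 309 and 267 steps on chromosome 2 (98664746 to 98665252) and 246, 75 and 88 steps at Camk1d. Near the start of chromosome 9 (3000006 to 3001530) the heights were 56, 106 and 100 steps. Sites that pile up reads in control libraries too stay open: peaks of lower rank in control replicates 1 and 3 overlapped the regions 0.101 times as often as random placements that also missed their top peaks (2 against 19.7), but regions with a control top peak had been left out there. Counted over the 30 loci with 50 kb on both sides, control replicate 1 had a top peak in 19, 1.51 times random placement (12.6 ± 2.48, SD), and control replicates 2 and 3 in 7 and 11 (0.508 and 0.857 times). Another 20 regions were called in exactly 4 equal-length lists. Most of these joined control replicate 1 with the mutant libraries, and the rest joined other libraries. Some lay in or beside the loci of mutant regions, as on chromosome 13 from 12797316 to 12799606 and from 12802050 to 12810944. On chromosome 5, a region from 15457740 to 15461569, 12 steps high in control replicate 1, lay beside the mutant region from 15462194 to 15464307. On chromosome 18 (68691833 to 68694644) the heights were 248 steps in control replicate 1 and 300, 92 and 80 in mutant replicates 1, 2 and 3. A few extended loci counted many times fits the data: counted as loci, the real split gave 39 against 43 for the highest other split, a ratio of 0.907. Copy number or strain differences between the mice used for each genotype remain a candidate explanation beside the mutation, and neither was tested.

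With 10 splits of the 6 libraries the share of splits cannot go under 0.1. For regions called in one group alone, the real split gave 88 and the highest other 47, and 1 of the splits, the real one, gave as many. With all peaks the real split gave 5987 regions and the highest other 23844. For genes the real split gave 50 and the highest other 53, and 3 splits gave as many, and with all peaks the counts were 1756 and 6000. The highest of the other splits in both full-list counts set control replicate 1 with mutant replicates 2 and 3, the 3 libraries of largest covered length, against the rest. For limma the real split called 0 regions and the highest other 1, and a real count of 0 leaves this comparison nothing to show.

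The X chromosome held 2.23%, 6.09% and 9.69% of the control peaks and 3.90%, 3.90% and 3.93% of the mutant peaks in replicates 1, 2 and 3. The Y chromosome held 0.00231%, 1.35% and 0.723% of the control peaks (2, 160 and 219 peaks) and 0.0388%, 0.0265% and 0.00584% of the mutant peaks (21, 109 and 30 peaks). The tallest peak was 248, 9 and 8 steps high in the control and 300, 309 and 267 steps high in the mutant libraries.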
